A study of Mus musculus with 39 samples.

How the data were processed

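Transcripts were measured with Affymetrix mouse 430 2.0 arrays in photoreceptors sorted by flow cytometry for GFP, which per the labels marks rod precursors and rods in wt and S-cone-like cells in ko. The series holds 39 arrays in 10 groups, 20 of wt and 19 of ko at 5 stages, with 3 arrays in ko E16 and 4 in each other group. Per the labels, RNA was amplified and biotin was added by the NuGEN protocol. The deposited table holds log2 values made by the authors, with RMA named in the labels as the tool and no version or settings. Values lay between 4.03 and 14.48. The authors also deposited detection calls, a text value of unit other (present or absent) for each probe set and stage, with replicates combined in a way that is not stated. The adult column of the calls was not assigned to a group; it entered only the question whether a probe set was present in any column, in the filter on detection calls and the choice of detected list members.

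Of 45101 probe sets, 64 were controls, 34945 were paired with exactly 1 gene, 932 with several genes and 9160 had no row in the gene table. Entrez identifiers of 34741 probe sets matched the RefSeq table, which changed 0 symbols. Each of 18193 genes was represented by the probe set with the highest mean over the 39 arrays, a choice that concerned the 9010 genes with more than 1 probe set. No further normalization and no filter on dim genes was applied. No 2 arrays were identical, and the highest correlation between any 2 arrays was 0.995. The number of arrays limits the precision. Each p-value measures the spread between arrays, and the labels do not say whether the arrays of a group came from separate animals.

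The groups were taken from the labels. A linear model with a mean for each group was fitted to all arrays in limma 3.58.1 under R 4.3.3, with empirical Bayes variances (29 residual and 2.81 prior degrees of freedom). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. The contrasts were ko against wt at each stage and each stage against the stage before it in each genotype, and an F test over 4 contrasts asked whether the genotype effect differed from that at E16. Adjusted p-values in the report come from these limma fits. Of 23 gene lists, fixed before the data were examined, 369 of 398 members were measured. The 22 lists with at least 5 measured members were tested with camera in limma (preset correlation 0.01), adjusted over 110 tests, and also with an estimated correlation and with fry. The sign of the median, the mean and the test differed in 22 of the 110 tests and in 0 of the 33 that were called. The list of sex-linked genes, with 4 measured members, was not tested, and 0 of its members were called between genotypes at any stage. This does not show that the groups were alike in sex, since Xist varied widely within groups. At 4 weeks it lay at 7.15, 9.94, 6.90 and 10.90 in ko and at 6.37, 11.04, 11.23 and 11.44 in wt. RNA quality was compared with exact two-sided permutation tests on the 3' minus 5' signal of Actb, with Gapdh as the alternative, whose lowest possible p was 0.0286. Overlaps of called genes were compared with independent draws by one-sided Fisher's exact tests.

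The genes named in the report were chosen by a rule fixed before the data were examined. It took the called genes with the largest differences whose arrays did not overlap (10 up and 10 down at P10 and 4 weeks, 5 and 5 at the other stages and for each step). It also took a set of photoreceptor genes at every stage, up to 4 members of each list with the largest difference at the stage described, and the 10 smallest p of the interaction. Unnamed clones and predicted models were passed over. Other called list members, genes shared by all stages and the genes shown for ko 4 weeks replicate 2 were named after their values were seen. Members without a probe set in the gene table were not analysed here.

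Replicate numbers were checked as possible pairs by correlating residuals of arrays with the same number. All pairs were positive only between ko P2 and ko E16 (3 pairs, r from 0.30 to 0.74) and between ko P6 and ko P2 (4 pairs, r from 0.13 to 0.84), and the numbers were otherwise not treated as pairs. With the replicate number as a block (replicate block), the counts were 146 against 182 genes for the ko E16 to P2 step and 119 against 120 for the ko P2 to P6 step.

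The model was tested on simulated arrays, built from the group means and residual spreads of the genes with independent noise, and with known changes added. These arrays lacked the differences in array spread and the correlation between genes of the real arrays. The counts of false calls below therefore hold for independent genes only. At 4 weeks the model called 30 of 67 genes changed by 1.5-fold, 50 of 67 by 2-fold and 63 of 66 by 4-fold, with 7 of 17993 unchanged genes called. At E16 it called 17 of 67, 41 of 67 and 59 of 66, with 3 of 17993 unchanged genes called. A shift of 0.5 (log2) added to a list was called in 20 of 20 draws, and 0 of 420 unchanged lists were called.

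Alternatives planned before the data were examined were cyclic loess and quantile normalization, filters at the median value and on the detection calls, every probe set or the mean of all probe sets of a gene, a minimum of 2-fold, trend and robust variances, array weights, the Actb 3' minus 5' signal as a covariate, fits of only the arrays compared, the replicate block, and each array left out in turn. The array weights were estimated gene by gene, since the default method did not converge. The alternatives chosen after seeing the data were listed separately, namely the array spread as a covariate and leaving out 6 doubted arrays together, which were the 5 arrays with a spread under 1.45 (ko E16 replicate 3, ko P2 replicate 4, ko P6 replicate 4, and wt P10 replicates 1 and 2) and ko 4 weeks replicate 2.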

Results

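Transcript levels were measured on Affymetrix mouse arrays in photoreceptors sorted for green fluorescent protein (GFP), which the Nrl promoter drove in both genotypes. Wild-type mice (wt) and mice without Nrl (ko), the transcription factor that directs photoreceptor precursors to the rod fate, were sampled at embryonic day 16 (E16), at postnatal days 2, 6 and 10 (P2, P6, P10) and at 4 weeks. Each of the 10 groups held 4 arrays, except ko E16 with 3, so that 20 wt and 19 ko arrays were compared. Signals were on the log2 scale, with array means between 6.94 and 7.01 and a spread over probe sets (SD) between 1.34 and 1.80. An array gives no count of molecules, and the number of arrays limits the precision. Values are given as log2 means ± SD, and differences as ko minus wt with their standard error (SE). A fold is given as "at least" where the deposited detection call of the dimmer group was absent. The calls for adults were not assigned to a group, so that folds of genes near background at 4 weeks are lower bounds.

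Nrl, the targeted gene, was lower in ko than in wt at every stage. In the 15 ko arrays from E16 to P10 its signal lay between 5.36 and 6.48, with an absent detection call, while the wt mean rose from 9.56 ± 0.82 (n = 4) at E16 to 10.83 ± 0.82, 11.64 ± 0.38, 11.92 ± 0.20 and 12.26 ± 0.05 (n = 4 each) at P2, P6, P10 and 4 weeks. The difference was -3.77 (SE 0.51) at E16, -4.82 at P2, -5.43 at P6, -6.09 at P10 and -5.74 (SE 0.47 each) at 4 weeks, with adjusted p from 5.47e-05 at E16 to 9.65e-11 at 4 weeks. The labels do not say where the probe set lies relative to the deleted part of the gene. At 4 weeks, 3 ko arrays held Nrl at 5.68 ± 0.09 and replicate 2 held it at 9.05. Genes of dividing and immature cells, chosen after their values were seen, were high in that array: Rrm2, a subunit of ribonucleotide reductase, at 11.73 against 5.33 ± 0.25 in the other 3 ko arrays (wt E16 mean 11.57), and the neuronal differentiation factor Sox11 at 12.67 against 6.97 ± 0.14 (12.93). Not all such genes followed wt E16, since the proliferation marker Mki67 lay at 10.63 (wt E16 mean 9.54) and the topoisomerase Top2a at 8.13 against 7.92 ± 0.12 (7.44). Gnat1, the rod transducin subunit, stayed at 7.76 in it, and the difference of Nrl at 4 weeks without this array was -6.58.

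**Figure D1:**
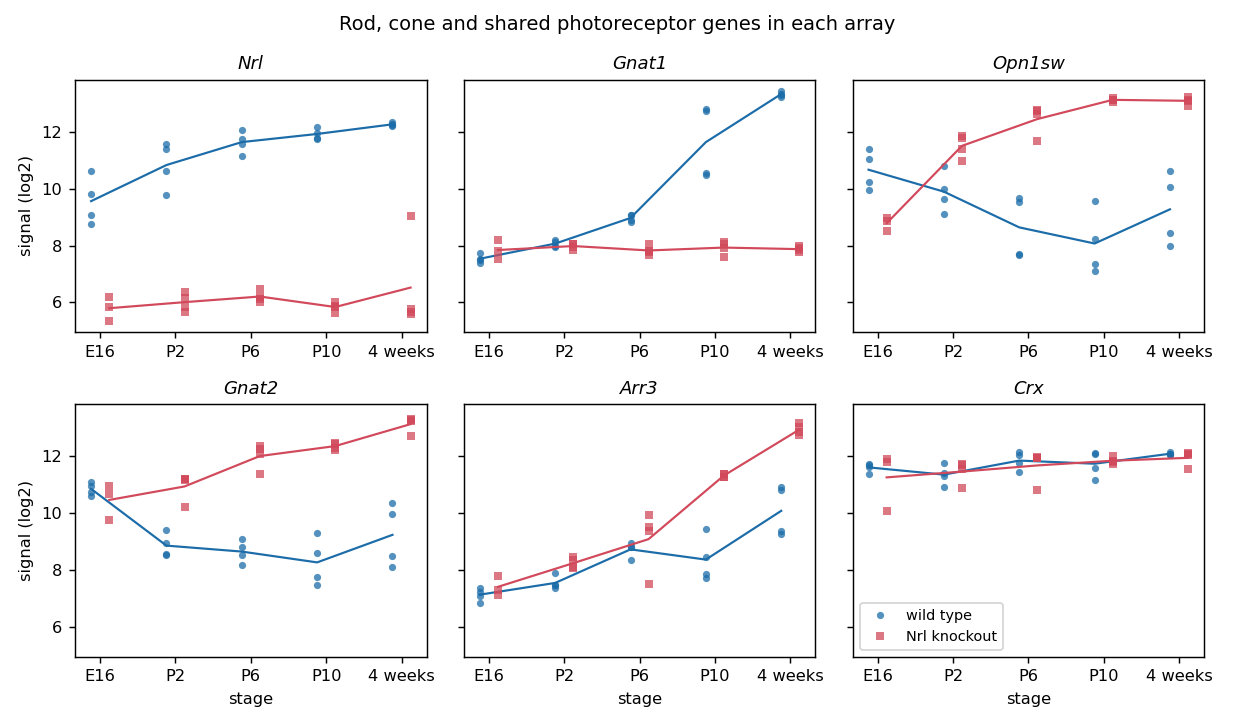
Signal (log2, y axis) of 6 photoreceptor genes in each array by stage (x axis), with circles for wild type, squares for Nrl knockout and lines through the group means. Nrl in ko lies between 5.36 and 6.48 from E16 to P10 and at 9.05 in 1 array at 4 weeks, and Opn1sw in ko rises from 8.78 at E16 to 13.12 at P10.

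**Figure D2:**
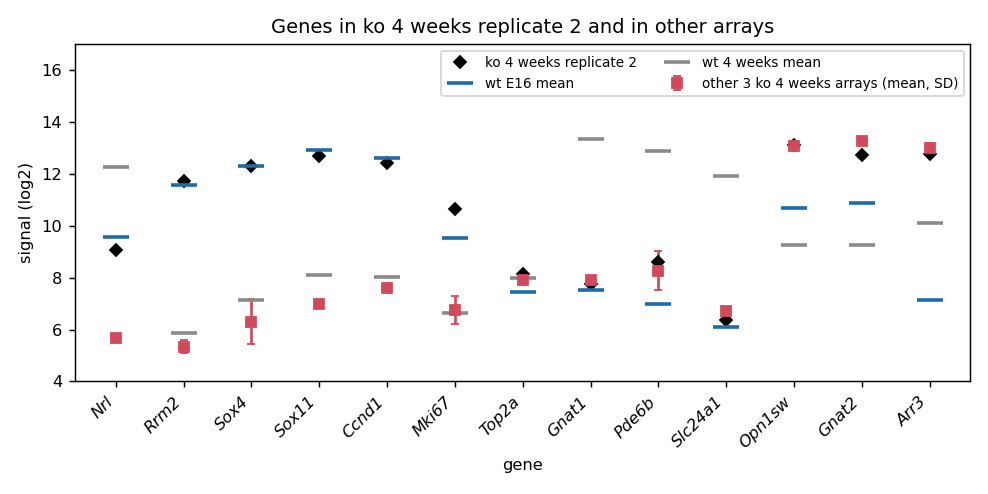
Signal (log2, y axis) of 13 genes (x axis) in ko 4 weeks replicate 2 (diamonds), in the other 3 ko 4 weeks arrays (squares, mean with SD) and in the means of wt E16 and wt 4 weeks (blue and grey bars). Rrm2 lies at 11.73 in replicate 2 and at 11.57 in wt E16, while Arr3 lies at 12.75 in replicate 2 and at 7.14 in wt E16.

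At E16, the comparison of ko with wt asked which genes differ at the earliest stage sampled. Lrp4, a receptor of the low-density lipoprotein receptor family, was at least 9.01-fold lower in ko (6.42 ± 0.21, n = 3, against 9.59 ± 1.13, n = 4), and Ctr9, a subunit of the PAF1 elongation complex, was 7.02-fold lower (8.22 ± 0.09 against 11.03 ± 0.11). Nefl, the neurofilament light chain of projection neurons, fell by 1.94 (SE 0.29), and Rbp3, the retinoid-binding protein that photoreceptors secrete, fell by 1.08 (SE 0.14). Ttc5, a cofactor of the p53 response, was at least 3.48-fold higher, and Rab13, a small GTPase of membrane traffic, was 2.24-fold higher in ko. Each of these genes kept its call with any 1 array left out. The long noncoding RNA Miat (at least 8.29-fold lower) and the prefoldin subunit Pfdn2 (at least 3.16-fold higher) also passed. Miat missed the threshold without any of 4 arrays and Pfdn2 without ko replicate 1 (highest adjusted p = 0.0672 and 0.056). Of the cone genes, Opn1sw, the short-wavelength opsin, was at 8.78 ± 0.23 in ko and 10.67 ± 0.67 in wt, a difference of -1.88 (SE 0.55) that did not pass (adjusted p = 0.0925), and Gnat2 and Arr3 did not differ beyond the spread either.

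The markers of amacrine, horizontal and ganglion cells were lower in ko at E16: 4 of 23 fell, and 9 when adjusted over the list alone, with adjusted p = 7.81e-08 for the list and 0.0324 with an estimated correlation. The 4 were Nefl, Nefm (-1.83), Pou4f1 (-1.23) and Gap43 (-1.14). Lists of energy metabolism were lower as well, glycolysis with 2 of 17 fallen (Pfkp and Aldoa; also 2 over the list alone; adjusted p = 0.00164) and oxidative phosphorylation with 0 fallen and 1 risen of 22 (Uqcrc1; 5 fallen over the list alone; adjusted p = 0.00017). Synapse genes (1 of 20 fell, Stx3, also 1 over the list alone) and retinal progenitor genes (1 of 19 fell, Six3, 5 over the list alone) were lower with adjusted p = 0.00191 and 0.0127. With an estimated correlation these 4 calls were lost (adjusted p = 0.544, 0.71, 0.629 and 0.71). Without ko E16 replicate 3, the array of lowest spread, the calls of oxidative phosphorylation, synapse and progenitor genes were lost too (adjusted p = 0.846, 0.205 and 0.893), and without wt E16 replicate 1 that of progenitor genes (0.124). The rod list was not called with all arrays (camera, adjusted p = 0.0592). It was called as lower without ko E16 replicate 3 (0.0486), wt E16 replicate 1 (0.00174) or the 6 doubted arrays (0.0328). The lens list was also called without ko E16 replicate 3 (0.0384) or wt E16 replicate 1 (0.0165). Markers of microglia and leukocytes were higher in ko, with 0 of 12 called over all genes and 3 risen over the list alone (adjusted p = 0.00046, and adjusted p = 0.283 with an estimated correlation). Only 4 of the 12 had a present detection call in any column, so that most of this list lay near background. Cd53, a leukocyte tetraspanin outside this list, was at least 2.19-fold higher in ko, a call lost without any of 4 arrays (highest adjusted p = 0.192, without wt replicate 1). The calls of Pfkp, Aldoa and Six3 were also lost without any of 2, 5 and 5 arrays (highest adjusted p = 0.0672, 0.211 and 0.153).

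In all, 205 of 18193 genes differed at E16 (56 higher and 149 lower in ko), 97 of them by at least 2-fold. The count was 101, 404, 76, 507, 60 and 114 without ko replicates 1 and 3 and wt replicates 1, 2, 3 and 4, and 17 when only these 7 arrays were fitted, where Lrp4, Rbp3, Ttc5, Rab13, Pfdn2, Cd53, Stx3, Six3, Pfkp and Aldoa lost their calls. It was 675 without the 6 doubted arrays, which were the 5 of lowest spread and ko 4 weeks replicate 2.

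At P2, rod genes were lower in ko. Cone genes were higher as a list, a call that was lost with an estimated correlation. Gnat2, the cone transducin subunit, was 4.23-fold higher (10.94 ± 0.48 against 8.86 ± 0.40, n = 4 each), and Pde6c, the cone phosphodiesterase, was 4.21-fold higher, although Pde6c missed the threshold without any of 5 arrays (highest adjusted p = 0.0738, without ko replicate 1). Among rod genes, Sag, the rod arrestin, was at least 5.39-fold lower, Pde6b, a rod phosphodiesterase subunit, at least 5.16-fold lower and Samd7, a repressor of other cell fates in rods, 3.56-fold lower. Lrp4 was 12.4-fold lower (8.34 ± 0.44 against 11.98 ± 0.14). Outside the photoreceptor lists, the purine nucleoside phosphorylase Pnp was 6.61-fold higher, the melatonin receptor Mtnr1a 3.44-fold higher and the immediate-early factor Egr1 5.27-fold lower. Opn1sw was at 11.51 ± 0.41 in ko and 9.90 ± 0.71 in wt and did not pass (adjusted p = 0.367).

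Of 18 rod genes 5 fell at P2, with the same number over the list alone (adjusted p = 2.51e-12, and 0.0324 with an estimated correlation), the 5th being Gngt1. Of 17 cone genes 2 rose, and 5 over the list alone (adjusted p = 1.36e-08; adjusted p = 0.0522 with an estimated correlation). The amacrine, horizontal and ganglion cell markers were lower again, with 1 of 23 fallen and 3 over the list alone (adjusted p = 2.85e-07, and 0.0324 with an estimated correlation). In wt replicate 1 the list lay at 7.08, nearer to ko (6.93 to 6.99) than to the other wt arrays (7.62 to 7.69). The 1 member was Tfap2b, an amacrine cell factor, whose call was lost without any of 7 arrays (highest adjusted p = 0.266, without wt replicate 2). Cell cycle and progenitor genes were lower with 0 members called in either way (adjusted p = 0.0255 and 0.0172). Both calls were lost with an estimated correlation (adjusted p = 0.722 and 0.71), and without ko replicate 4 (0.104 and 0.166), wt replicate 2 (0.298 each) or wt replicate 3 (0.295 and 0.116). Immediate-early genes were lower with 1 of 15 fallen (3 over the list alone; adjusted p = 0.00152, and adjusted p = 0.256 with an estimated correlation). In all, 63 genes differed at P2 (23 higher and 40 lower). The count was 33, 29, 32, 119, 34, 26 and 35 without ko replicates 1, 2 and 3 and wt replicates 1, 2, 3 and 4, 205 without the 6 doubted arrays and 38 when only these 8 arrays were fitted, where Sag, Mtnr1a and Tfap2b lost their calls.

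At P6, Opn1sw rose by 3.81 (SE 0.51) in ko (12.45 ± 0.51 against 8.64 ± 1.10, n = 4 each), Gnat2 10.3-fold higher (12.01 ± 0.44 against 8.65 ± 0.39), and the potassium channel subunit Kcne2 11.4-fold higher. Socs3, an inhibitor of cytokine signalling, was 10.4-fold higher, and Pcp2, a modulator of G proteins known from bipolar and Purkinje cells, 10.7-fold higher. Lrp4 was at least 64.3-fold lower (6.57 ± 0.32 against 12.58 ± 0.31), Pde6b 23.2-fold lower (6.94 ± 0.16 against 11.48 ± 0.38), Samd7 6.77-fold lower and Gnb1, the beta subunit of rod transducin, 4.42-fold lower. Slc17a7, the vesicular glutamate transporter of photoreceptor synapses, was 3.92-fold higher in ko, and Sall3, a factor of cone and horizontal cell genes, at least 2.92-fold higher. Each gene of this paragraph kept its call with any 1 array left out.

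Of 17 cone genes 10 rose at P6, and 11 over the list alone (adjusted p = 2.19e-24, and 0.000343 with an estimated correlation). Of 18 rod genes 7 fell, and over the list alone 8 fell and 1 rose (adjusted p = 3.11e-12, and 0.0324 with an estimated correlation). Of the 23 amacrine, horizontal and ganglion cell markers 2 fell, Tfap2b (-3.50) and Gad1 (-2.78), which makes the transmitter GABA, and 6 over the list alone (adjusted p = 0.00017; adjusted p = 0.156 with an estimated correlation). The call of Gad1 was lost without any of 4 arrays (highest adjusted p = 0.0805, without wt replicate 2). Lists with smaller shifts were cilium transport, lower with 0 of 25 called (adjusted p = 0.0242), oxidative phosphorylation, higher with 0 of 22 called (0.0141), and pigment epithelium, higher with Tyrp1 and Dct risen of 11 (2 over the list alone; 0.0416). Only 4 pigment epithelium genes had a present detection call in any column. With an estimated correlation the calls of these 3 lists were lost (adjusted p = 0.722, 0.722 and 0.71). They were lost without single arrays as well: cilium transport without ko replicate 4 (adjusted p = 0.3) or wt replicate 3 (0.245), oxidative phosphorylation without ko replicate 1 (0.255), ko replicate 3 (0.102) or wt replicate 4 (0.59), and pigment epithelium without ko replicate 4 (0.115, with a median of -0.02 against 0.10 with all arrays), wt replicate 2 (0.104) or wt replicate 3 (0.229). In all, 281 genes differed at P6 (145 higher and 136 lower), 161 of them by at least 2-fold. The count was 171, 167, 147, 164 and 175 without ko replicates 1, 2 and 3 and wt replicates 1 and 2, and 757 without the 6 doubted arrays. When only these 8 arrays were fitted it was 201, and Slc17a7 and Sall3 lost their calls.

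At P10, cone genes were again higher and rod genes lower in ko. Opn1sw was at least 33.2-fold higher in ko (13.12 ± 0.06 against 8.07 ± 1.12, n = 4 each), Guca1a, an activator of guanylate cyclase, 32.1-fold higher (12.11 ± 0.26 against 7.11 ± 1.07), Gnat2 was higher by 4.09 (SE 0.38) and the cone arrestin Arr3 7.77-fold higher (11.33 ± 0.06 against 8.37 ± 0.77). Guca1a was counted in the cone list. In wt it rose later, from P10 to 4 weeks, so that its difference at P10 does not mark cones alone. Genes outside the photoreceptor lists rose as well, among them the transcription factor Insm2 (at least 15.5-fold), the Hippo pathway scaffold Wwc1 (15.1-fold), the glycerol-phosphate acyltransferase Gpat3 (at least 14.6-fold), Moxd1, a relative of dopamine beta-hydroxylase (at least 12.6-fold), and the repressor Klf3 (11.1-fold). Gnat1 was 13.1-fold lower (7.93 ± 0.23 against 11.64 ± 1.30), Pde6b 22.7-fold lower (7.59 ± 0.14 against 12.09 ± 0.46), the rod channel subunit Cnga1 at least 7.43-fold, the rod protein of membrane traffic Reep6 7.19-fold and the rod ion exchanger Slc24a1 6.07-fold lower. Gnat1 was called present in ko at P10 but absent at like levels in ko at E16 (7.84) and P2 (7.98), so that its fold is a lower bound. Dhrs3, a retinal reductase, was at least 4.66-fold lower, and Shisa2, a modulator of Wnt and FGF receptors, 6.77-fold lower. Each of these genes kept its call with any 1 array left out. Crx, the regulator shared by rods and cones, was at 11.85 ± 0.12 in ko and 11.74 ± 0.45 in wt and did not pass at any stage.

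Of 17 cone genes 12 rose at P10, and over the list alone 13 rose and 2 fell (adjusted p = 2.42e-31, and 6e-05 with an estimated correlation). Of 18 rod genes 12 fell, and 13 over the list alone (adjusted p = 2.19e-24, and 0.00128 with an estimated correlation). Regulators of photoreceptor fate were higher with Sall3 (2.43), Mef2d (1.68) and Otx2 (1.43) risen of 18, and 4 over the list alone (adjusted p = 0.00017; adjusted p = 0.0767 with an estimated correlation). Synapse genes were higher with Slc17a7 (1.83) and Nrxn3 (1.70) risen of 20 (over the list alone 5 rose and 1 fell; adjusted p = 0.00861), and immediate-early genes with Fos (1.67) and Nr4a1 (0.65) risen of 15 (5 over the list alone; adjusted p = 0.000908). Amacrine, horizontal and ganglion cell markers were lower with Tfap2b (-2.69), Gad1 (-2.51) and Calb1 (-1.22) fallen of 23 (also 3 over the list alone; adjusted p = 0.00347). With an estimated correlation the synapse, immediate-early and amacrine calls were lost (adjusted p = 0.71, 0.227 and 0.371). The synapse call was lost without wt P10 replicate 1 (adjusted p = 0.0738) or replicate 2 (0.184), and without the 6 doubted arrays the synapse list turned direction and was not called (median -0.17). Without these arrays the immediate-early and regulator calls were lost as well (adjusted p = 0.481 and 0.122, medians 0.05 and 0.07). That fit gained calls too. Shared photoreceptor, cilium transport and glycolysis genes were lower (adjusted p = 0.0117, 0.0019 and 0.00191, medians -0.41, -0.31 and -0.47). Pigment epithelium genes were called as well (0.0368, median 0.15). Glycolysis was also called without ko replicate 2 (0.0321), wt replicate 1 (0.0316) or wt replicate 2 (0.0204). Without wt replicate 3, cilium transport was called with a median of 0.19 (0.0207). The calls of Mef2d, Otx2 and Fos were lost only without wt P10 replicate 2 (adjusted p = 0.0621, 0.0546 and 0.067), and that of Tfap2b only without wt P10 replicate 4 (0.0528). Those of Nrxn3 and Gad1 were lost without any of 2 and 5 arrays (highest adjusted p = 0.0854 and 0.103).

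In all, 512 genes differed at P10 (354 higher and 158 lower), 323 of them by at least 2-fold. The higher genes made up 69.1%, and 56.2% of the 800 genes called after cyclic loess. Each wt P10 array correlated with the others of its group with a mean r of 0.888 to 0.935. Replicate 3 correlated best with a wt 4 weeks array and replicate 4 with a wt P6 array. The count was 1536 without wt replicate 3, 293 and 316 without ko replicates 2 and 4, and 1197 without the 6 doubted arrays, 2 of which are wt P10 replicates 1 and 2. When only these 8 arrays were fitted it was 210, and Slc24a1, Dhrs3, Mef2d, Otx2, Slc17a7, Nrxn3 and Fos lost their calls. Actb signal toward the 3' end was also higher in ko than in wt at P10, by 0.77 (1.77 ± 0.25 against 1.00 ± 0.33, n = 4 each, higher in all ko than in all wt arrays); the exact two-sided permutation p was 0.0286, the smallest that 4 against 4 arrays allow, and 0.143 after adjustment over the 5 stages.

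At 4 weeks, in mature photoreceptors, rod genes were lower and cone genes higher in ko. Gnat1 was 43.9-fold lower in ko (7.87 ± 0.09 against 13.33 ± 0.08, n = 4 each), Slc24a1 38.7-fold (6.62 ± 0.21 against 11.90 ± 0.29), Pde6b 22.8-fold, the potassium channel Kcnj14 21.8-fold, Cnga1 18.2-fold and Reep6 17.4-fold lower. The transporters Slc22a29 and Abca13 were 25.8-fold and 16.6-fold lower. The chloride channel regulator Clca1 was 31.3-fold higher (10.72 ± 0.46 against 5.75 ± 0.30), the fatty acid binding protein Fabp7 31.1-fold, the cone channel subunit Cngb3 18.8-fold, Gnat2 14.9-fold, Opn1sw 14.1-fold and the cone phosphodiesterase subunit Pde6h 11.8-fold higher. Opn1mw, the medium-wavelength opsin, was 2.98-fold higher (8.61 ± 0.25 against 7.04 ± 0.67) and was not called at an earlier stage. The wt arrays differed among themselves: replicates 1 and 4 held Opn1sw at 10.64 and 10.06 and Gnat2 at 10.36 and 9.99, against 7.98, 8.43, 8.10 and 8.51 in replicates 2 and 3. The means of the amacrine, horizontal and ganglion cell markers (7.75 and 7.53 against 6.96 and 6.93) and of the bipolar cell markers (7.69 and 7.70 against 7.25 and 7.33) were higher in the same 2 wt arrays. The retinol dehydrogenases Dhrs3 and Rdh12 were 11.4-fold and 3.31-fold lower, the glycolytic enzymes Pfkp and Aldoc 4.06-fold and 3.19-fold lower, and Prdm1, a regulator that favours photoreceptor over bipolar fate, was 3.16-fold higher. Each of the called genes kept its call with any 1 array left out.

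Of 18 rod genes 14 fell at 4 weeks, with the same number over the list alone (adjusted p = 5.03e-55, and 8.14e-06 with an estimated correlation). Of 17 cone genes 13 rose, again with the same number over the list alone (adjusted p = 4.87e-36, and 2.62e-05 with an estimated correlation). The genes shared by both photoreceptor types were lower on balance, with Rp1 and Fscn2 fallen and Cdhr1 and Rbp3 risen of 19 (7 fell and 2 rose over the list alone; adjusted p = 0.000721). Lower lists were glycolysis, with Pfkp and Aldoc fallen and Pfkm risen of 17 (7 fell and 1 rose over the list alone; adjusted p = 0.00017), and cilium transport, with Bbs7, Bbs9 and Ift88 fallen of 25 (5 fell and 1 rose over the list alone; adjusted p = 0.0113). Higher lists were immediate-early genes, with Egr1, Jun, Nr4a1 and Ddit3 risen of 15 (5 over the list alone; adjusted p = 0.00915), and microglia and leukocytes, with Tyrobp risen of 12 (2 over the list alone; adjusted p = 0.0185). With an estimated correlation these 5 calls were lost (adjusted p = 0.428, 0.407, 0.71, 0.411 and 0.609). Only 4 of the 12 microglia and leukocyte markers had a present detection call in any column. Progenitor genes were higher with Six6 (1.70) and Dll1 (0.54) risen of 19 (3 over the list alone; adjusted p = 0.00061) and cell cycle genes with 0 of 21 called in either way (adjusted p = 0.0366), calls that were lost with an estimated correlation (adjusted p = 0.54 and 0.722). Without ko 4 weeks replicate 2 the progenitor call was lost (adjusted p = 0.389), the cell cycle genes turned direction (median -0.02, adjusted p = 0.585), and the immediate-early, microglial and shared photoreceptor calls missed the threshold (adjusted p = 0.0916, 0.0515 and 0.0515), and the amacrine, horizontal and ganglion cell markers were called as lower (median -0.14, adjusted p = 0.0103). This left 5 called lists against 9 with all arrays. The medians of the immediate-early, microglial and shared photoreceptor lists were 0.16, 0.14 and -0.22 without that array and 0.18, 0.11 and -0.46 with all arrays. The cell cycle call was also lost without wt replicate 1 (adjusted p = 0.118) and the cilium call without ko replicate 1 (0.0811). The calls of Rp1, Bbs9 and Tyrobp were lost without any of 4, 6 and 5 arrays (highest adjusted p = 0.0793, 0.11 and 0.192, each without ko 4 weeks replicate 2). That of Jun was lost only without ko 4 weeks replicate 2 (0.0795) and that of Bbs7 only without ko 4 weeks replicate 1 (0.0654).

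In all, 860 genes differed at 4 weeks (383 higher and 477 lower), 483 of them by at least 2-fold. The count lay between 712 and 779 with any 1 array left out, was 1389 without the 6 doubted arrays and 2028 with the array spread as a covariate, where 860 of the 860 genes were called again. When only these 8 arrays were fitted it was 873, and Jun, Nr4a1 and Tyrobp lost their calls.

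**Figure D3:**
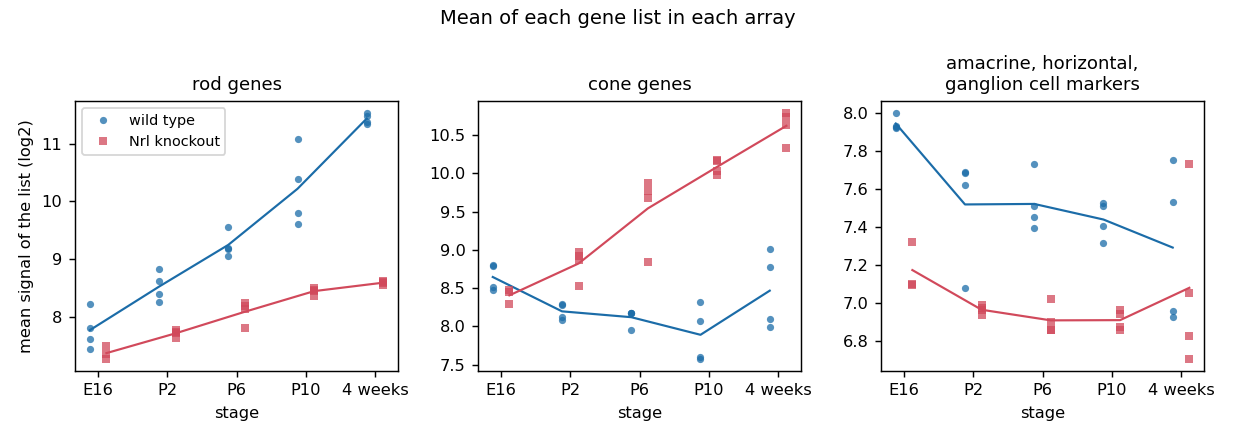
Mean signal (log2, y axes of different range) of the rod genes, the cone genes and the markers of amacrine, horizontal and ganglion cells in each array by stage (x axis), with circles for wild type, squares for Nrl knockout and lines through the group means. The rod mean in wt lies between 11.3 and 11.5 at 4 weeks, while all ko arrays stay below 8.7 at all stages.

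Of the genes that differed between genotypes, 3 were higher (1500011B03Rik, the phosphodiesterase Gdpd3 and Rtkn2) and 4 were lower in ko (Nrl, Lrp4, Ctr9 and the chromatin factor Mllt10) at all 5 stages, and these are named because the count is small. Of the 354 genes higher at P10, 155 were also higher at 4 weeks, where independent draws would share 7.45 (Fisher's exact test, one-sided p = 2.88e-173). Of the 158 lower at P10, 70 were lower at 4 weeks, against 4.14 for independent draws (Fisher's exact p = 1.29e-68). The 145 higher and 136 lower genes of P6 shared 79 and 42 with P10, against 2.82 and 1.18 for independent draws. The stages share no arrays, but all contrasts use the same estimate of the spread of a gene, which favours calls of the same genes at several stages. Genes are also not independent of each other, so that these p-values describe an overlap across genes only.

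Whether the genotype effect itself changed after E16 was tested with an F test over the 4 later stages, and 571 of 18193 genes (3.14%) passed. The smallest p belonged to Moxd1 (effect raised by 5.47 from E16 to P10; adjusted p = 2.11e-12), Slc22a29 (-5.36 from E16 to 4 weeks) and Clca1 (4.92 from E16 to 4 weeks). The next were Arhgdib with 2.59, Kcnj14 with -4.48, Gnat1 with -5.76, the cone gene Ccdc136 with 2.92, Abca13 with -4.15, the galactosidase Glb1l3 with -2.59 and C4bp-ps1 with -3.14, each from E16 to 4 weeks (adjusted p from 9.97e-12 to 5.21e-09). Opn1sw, Gnat2, Arr3 and Opn1mw passed as well (adjusted p = 6.55e-07, 4.05e-06, 0.000268 and 0.00104), whereas Nrl, Crx and Thrb, the cone thyroid hormone receptor, did not (0.249, 0.927 and 0.487). For Nrl (unadjusted p = 0.0195) ko 4 weeks replicate 2 raised the SD of its group to 1.69, so that a constant effect is not shown. The group means of Thrb, called present from E16 to P10, lay between 5.64 and 5.95. That is near Nrl in ko at E16 (5.80), which was called absent, so that a difference may be hidden. The count was 1018 without wt P10 replicate 3 and 1297 without the 6 doubted arrays.

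Development in the sorted wt cells was followed over 4 steps. From E16 to P2, Atoh7, the factor of ganglion cell competence, was at least 7.52-fold lower (7.11 ± 0.21 against 10.03 ± 0.52, n = 4 each), Slc17a6, a vesicular glutamate transporter, 6.69-fold lower, Kcnab1, a potassium channel subunit, 8.48-fold lower and Gnat2 3.99-fold lower. Pde6b was at least 4.88-fold and Samd7 3.82-fold higher. Of the photoreceptor lists, 3 of 18 rod genes rose (Pde6b, Samd7 and Sag; 7 over the list alone) and 4 of 17 cone genes fell (Gnat2, Pde6c, Cngb3 and Otop3; 6 over the list alone, with 1 risen). From P2 to P6, Isl1, a LIM homeodomain factor, was 7.34-fold higher (11.89 ± 0.21 against 9.01 ± 0.96), the hormone-responsive factor Klf9 6.50-fold, the potassium channel Kcnma1 5.14-fold and Pde6b 4.55-fold higher. Isl1 is also a member of the bipolar cell list. The mean of that list rose in wt from 7.12 at P2 to 7.44 at P6, with a median change of -0.02. Whether the mix of sorted cells changed between stages in either genotype was not tested. From P6 to P10, Gnat1 rose 6.35-fold (11.64 ± 1.30 against 8.97 ± 0.12) and Slc24a1 at least 7.21-fold, while Insm2 was at least 10.5-fold lower and Fabp7 4.50-fold lower. The P10 mean of Gnat1 lay between 10.54 and 10.49 in replicates 1 and 2 and 12.72 and 12.81 in replicates 3 and 4. From P10 to 4 weeks, Guca1a was 33.6-fold higher (12.18 ± 0.26 against 7.11 ± 1.07), the kinase Sgk1 27.5-fold, Slc22a29 15.8-fold and Guca1b 12.0-fold higher, while Sox4, a factor of immature neurons, was 11.4-fold and the neuronal tubulin Tubb2b 9.22-fold lower. Each of these genes kept its call with any 1 array left out. With only the arrays compared the counts were 7017, 16, 4 and 87 over the 4 steps, and the 4 genes named from P6 to P10, Isl1 and Guca1b lost their calls.

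Of 18 rod genes limma called 2 as risen in wt from P2 to P6 (Pde6b and Gngt1), 5 from P6 to P10 and 10 from P10 to 4 weeks (6, 12 and 13 over the list alone). No list was tested as a set over the steps. At the last step 6 of 17 glycolysis genes rose (10 over the list alone), with Hk2 at 3.43 and Aldoc at 2.52. The counts of changed genes were 722 (200 higher), 27 (25 higher), 64 (18 higher) and 971 (773 higher) for the 4 steps. The shares higher moved with the scaling at the later steps, from 28.1% to 49.2% after cyclic loess from P6 to P10 and from 79.6% to 63.4% after quantile normalization from P10 to 4 weeks. For the E16 to P2 step the count was 128, 1485 and 214 without wt E16 replicates 1, 2 and 3, and 203 and 211 without wt P2 replicates 1 and 4. For P2 to P6 it was 12, 13, 14, 14 and 12 without wt P2 replicates 3 and 4 and wt P6 replicates 1, 2 and 3. For P6 to P10 it was 249 without wt P10 replicate 4, and 38 and 35 without wt P6 replicates 1 and 2. For P10 to 4 weeks it was 3963, 503 and 479 without wt P10 replicates 3, 1 and 2, and 632 without wt 4 weeks replicate 1.

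In ko, the E16 to P2 step raised Moxd1 7.62-fold (9.35 ± 0.39, n = 4, against 6.42 ± 0.42, n = 3), the secreted protease Htra1 5.61-fold, Insm2 4.54-fold and the cofactor Lmo2 4.30-fold, and lowered Atoh7 at least 6.19-fold. Opn1sw was 6.60-fold higher, a call lost without ko E16 replicate 1 or 2 (highest adjusted p = 0.0809). From P2 to P6, Kcne2 was 11.1-fold higher (11.70 ± 0.97 against 8.22 ± 0.23, n = 4 each), Klf9 10.6-fold, Isl1 10.4-fold and Sag at least 5.80-fold higher, while Rrm2 was 26.8-fold lower (6.13 ± 0.35 against 10.88 ± 0.51) and the Wnt agonist Rspo2 at least 7.45-fold lower. From P6 to P10, Guca1a was 8.05-fold higher (12.11 ± 0.26 against 9.10 ± 1.21), the lactate transporter Slc16a1 5.72-fold and Arr3 4.71-fold higher, and Htra1 4.40-fold lower. From P10 to 4 weeks, Opn1mw was 4.56-fold higher (8.61 ± 0.25 against 6.42 ± 0.10), Sgk1 5.40-fold and the matrix protein Vtn 6.15-fold higher, while Isl1 was 6.14-fold and the membrane protein Tmem215 6.98-fold lower. Apart from Opn1sw, each of these genes kept its call with any 1 array left out. With only the 7 arrays compared, however, limma called 0 genes from E16 to P2, so that every call named for this step was lost. In that fit 1006 of 18193 genes had an unadjusted p under 0.05, near the share of 0.05 that chance alone gives.

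Of 17 cone genes limma called 1 (Opn1sw), 2 (Guca1a and Kcne2), 3 (Arr3, Pde6h and Guca1a) and 2 (Opn1mw and Arr3) as risen over the 4 ko steps, and 1, 3, 3 and 4 over the list alone. Guca1a also rose in wt from P10 to 4 weeks, so that this member does not mark cones alone. Of 18 rod genes limma called 3 as risen from P2 to P6 (Gngt1, Pde6g and Sag), 3 from P6 to P10 (Gngt1, Sag and Samd7) and 0 at the other 2 steps, with the same numbers over the list alone. The median change of the rod list was 0.23, 0.01, 0.13 and 0.16 over the 4 steps, and differences between steps were not tested. Shared photoreceptor genes rose from P2 to P6 with 7 of 19 (10 over the list alone), among them Rcvrn (2.26) and Rp1l1 (2.21), and synapse genes with 6 of 20 (8 over the list alone), among them Slc17a7 (2.04) and Cplx4 (1.94). At the last step the call of Arr3 was lost without any of 5 arrays (highest adjusted p = 0.0818). Over the 4 ko steps, 182 (46 higher), 120 (96 higher), 250 (117 higher) and 189 (131 higher) genes changed. The shares higher were 25.3% for E16 to P2 and 55.0% after quantile normalization, and 69.3% and 56.2% for P10 to 4 weeks. For E16 to P2 the count was 7398 without ko E16 replicate 3, whose mean r within its group was 0.832 against 0.903 and 0.913 for the other arrays. It was 17 and 31 without ko E16 replicates 1 and 2, and 85, 83 and 70 without ko P2 replicates 1, 2 and 3. For P2 to P6 it was 73, 65 and 77 without ko P2 replicates 2, 3 and 4, and 63, 65, 55 and 280 without ko P6 replicates 1, 2, 3 and 4. For P6 to P10 it was 137, 109, 97 and 427 without ko P6 replicates 1, 2, 3 and 4, and 138, 105, 121 and 98 without ko P10 replicates 1, 2, 3 and 4. For P10 to 4 weeks it was 119 and 123 without ko P10 replicates 3 and 4, and 112 and 114 without ko 4 weeks replicates 3 and 4.

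The genotypes shared 64 of the genes lowered and 8 of those raised from E16 to P2, where independent draws would share 3.90 and 0.506 (Fisher's exact test, one-sided p = 3.02e-62 and 3.38e-08). From P2 to P6 they shared 13 raised genes against 0.132 (Fisher's exact p = 5.22e-24) and 0 lowered genes, of 2 in wt and 24 in ko. From P6 to P10 they shared 1 raised and 4 lowered genes against 0.116 and 0.336 (Fisher's exact p = 0.11 and 0.000351). From P10 to 4 weeks they shared 57 raised and 12 lowered genes against 5.57 and 0.631 (Fisher's exact p = 2.87e-43 and 1.14e-12).

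**Figure D4:**
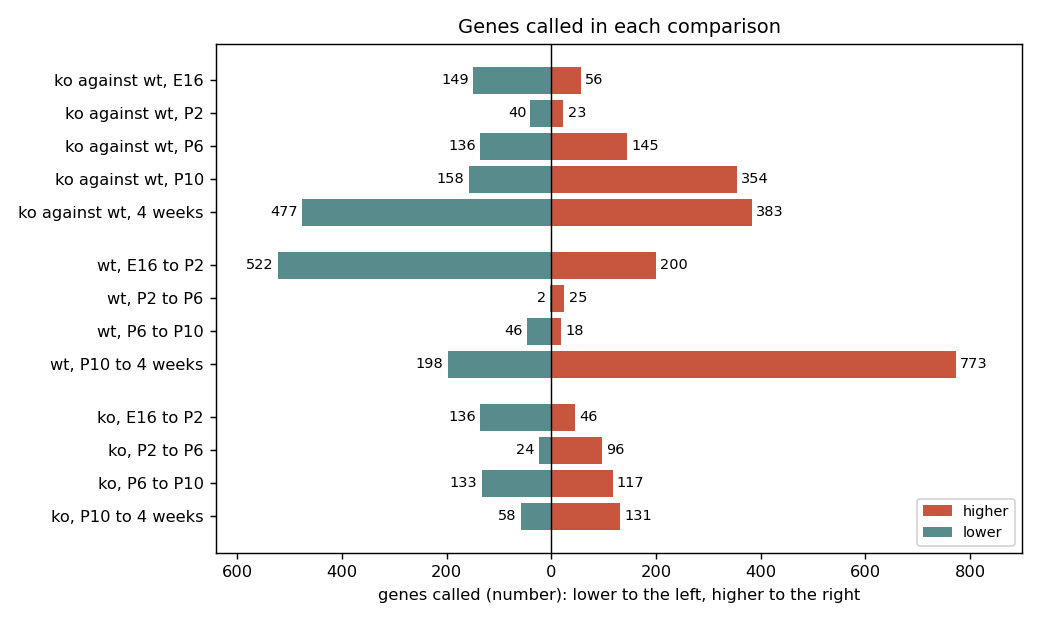
Number of genes called in each comparison (adjusted p under 0.05 within the comparison), with genes lower in the group named by the bar to the left of 0 and genes higher to the right (x axis). For ko against wt the bars give ko relative to wt, from 23 higher and 40 lower at P2 to 383 higher and 477 lower at 4 weeks, and for the steps they give the later stage relative to the earlier.

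The arrays differed in the spread of their signals by a measure that the groups did not explain. The leading principal component of all genes held 37.5% of the variance and followed this spread with r = 0.998 (Spearman coefficient = 0.994; permutation p = 1e-05 for each, the smallest that the draws allow; r = 0.998 without the 2 farthest arrays; 39 arrays). Within groups, the spread rose with the Actb 3' minus 5' signal (r = 0.766, permutation p = 1e-05, adjusted 2e-05; Spearman coefficient = 0.774, p = 2e-05; r = 0.756 without the 2 farthest arrays) and fell with that of Gapdh (r = -0.512, permutation p = 0.0549; Spearman coefficient = -0.416, p = 0.0439; r = -0.394 without the 2 farthest), the 2 relations computed. The spread itself did not differ between ko and wt beyond the spread of replicates at any stage (exact permutation p from 0.486 to 0.714), nor did Actb at the stages other than P10 (p from 0.0857 to 0.457) or Gapdh at any stage (p from 0.114 to 0.943).

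**Figure D5:**
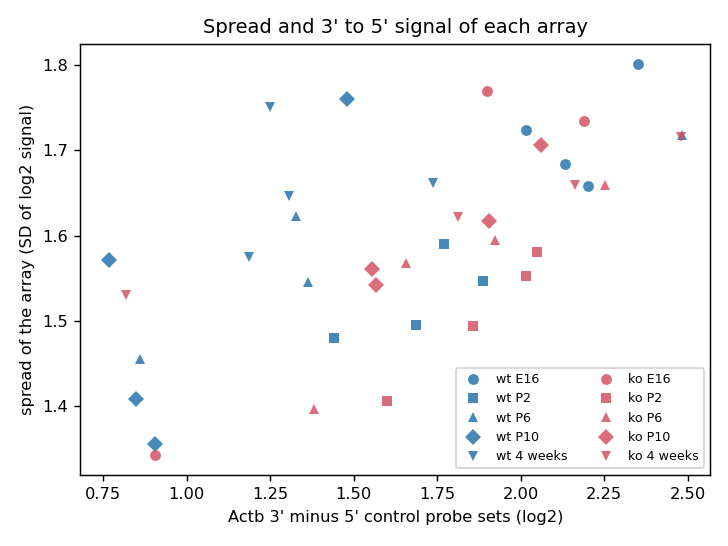
Spread of each array (SD of log2 signal, y axis) against the difference between its 3' and 5' Actb control probe sets (log2, x axis), with colour for genotype and shape for stage. The spread lies between 1.34 and 1.80, and within groups the measures were correlated with r = 0.766.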

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

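The tests on ko 4 weeks replicate 2, on the amacrine, horizontal and ganglion cell markers, on the relation of the array spread to RNA quality, genotype and stage, and on the splits within pairs of replicate numbers were chosen after the result was seen. So were the splits with the array spread as a covariate. The other regroupings of arrays and the quantile normalization were planned. Single arrays stood apart from the other 3 of their group by Dixon's test in 28 of 277 groups of gene values, 18 of 207 groups of list means and 1 of 27 groups of array measures. Chance flags about 1 in 20 groups, or 13.85, 10.35 and 1.35 of these. The arrays ko 4 weeks replicate 2 and ko P6 replicate 4 gave 9 of the values each.

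ko 4 weeks replicate 2 held Bbs9 at 8.23 (others 8.52 to 8.56), Crx at 11.55 (others 12.07 to 12.11) and Gnat2 at 12.72 (others 13.24 to 13.31). That array also held Jun at 11.88 (others 10.24 to 10.38), Nrl at 9.05 (others up to 5.77) and Vtn at 10.11 (others from 10.86). That array also held the mean of cell cycle genes at 9.10 (others 7.34 to 7.35), the mean of progenitor genes at 8.54 (others 7.01 to 7.11) and the mean of Wnt and BMP genes at 8.53 (others 7.96 to 8.05). ko P6 replicate 4 held Crx at 10.84 (others 11.95 to 12.00), Isl1 at 9.56 (others 11.23 to 11.49) and Kcne2 at 10.25 (others 12.14 to 12.23). That array also held Klf9 at 9.75 (others 11.27 to 11.56), Opn1sw at 11.68 (others 12.63 to 12.76) and Sall3 at 6.09 (others 7.46 to 7.72). That array also held Socs3 at 9.10 (others 10.87 to 11.09), the mean of Wnt and BMP genes at 8.26 (others 8.15 to 8.16) and the mean of sex-linked genes at 8.40 (others 8.91 to 8.96). ko P2 replicate 4 held Gnat2 at 10.23 (others 11.16 to 11.20), Pde6c at 10.50 (others 11.18 to 11.31) and the mean of shared photoreceptor genes at 8.49 (others 8.74 to 8.80). wt 4 weeks replicate 1 held Clca1 at 6.20 (others 5.56 to 5.64), Tyrobp at 6.34 (others 6.03 to 6.07) and the mean of blood genes at 6.45 (others 6.66 to 6.68). wt P10 replicate 3 held Mef2d at 11.44 (others 9.21 to 9.57), Moxd1 at 5.72 (others 6.22 to 6.25) and Slc22a29 at 7.66 (others 6.45 to 6.62).

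wt P2 replicate 1 held Isl1 at 7.57 (others 9.38 to 9.58), Tfap2b at 7.56 (others 10.13 to 10.62) and the mean of amacrine, horizontal and ganglion cell markers at 7.08 (others 7.62 to 7.69). wt P2 replicate 2 held Atoh7 at 7.42 (others 7.01 to 7.01), the mean of immediate-early genes at 8.36 (others 8.06 to 8.09) and the mean of bipolar cell markers at 7.09 (others 7.13 to 7.13). ko P10 replicate 2 held Reep6 at 7.51 (others 7.12 to 7.18) and the mean of immediate-early genes at 8.56 (others 8.29 to 8.33). wt E16 replicate 1 held the mean of amacrine, horizontal and ganglion cell markers at 8 (others 7.92 to 7.93) and the mean of vessel markers at 6.93 (others 6.73 to 6.76). wt P6 replicate 3 held Slc24a1 at 7.29 (others 6.39 to 6.43) and the mean of apoptosis genes at 7.81 (others 7.74 to 7.75). ko 4 weeks replicate 3 held the mean of glycolysis genes at 10.18 (others 10.15 to 10.15). ko P10 replicate 3 held the mean of microglia and leukocyte markers at 6.83 (others 6.92 to 6.93). ko P2 replicate 1 held Opn1mw at 6.02 (others 6.16 to 6.18). ko P6 replicate 1 held the Gapdh 3' minus 5' signal at 2.18 (others 2.73 to 2.82).

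wt 4 weeks replicate 4 held the mean of lens genes at 6.81 (others 7.09 to 7.12). wt E16 replicate 2 held Pfkp at 9.29 (others 9.79 to 9.87). wt P6 replicate 2 held Gad1 at 9.56 (others 8.56 to 8.63). wt P6 replicate 4 held the mean of cone genes at 7.95 (others 8.17 to 8.18).

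The genotype effect differed between stages, by the F test of the difference itself, for Moxd1, Slc22a29 and Clca1 (adjusted p = 2.11e-12 each), Arhgdib (9.97e-12), Kcnj14 (1.52e-11) and Gnat1 (2.74e-11). The same test passed for Ccdc136 and Abca13 (3.05e-10 each), Glb1l3 (1.68e-09) and C4bp-ps1 (5.21e-09), and for the cone genes Opn1sw (6.55e-07), Gnat2 (4.05e-06), Arr3 (0.000268) and Opn1mw (0.00104).

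Nrl at 9.05 in ko 4 weeks replicate 2 went with transcripts of dividing and immature cells. Rods of 4-week wt mice are argued against as the source, since the share of 9.85% that Nrl would need would raise 13 rod genes by a median of 1.19, and they changed by -0.1437 (SE 0.11). A wrong label, by which the whole array would be wt E16 (mean r 0.972 with wt E16, 0.954 with its own group), is argued against as well, since 45 genes at least 8-fold higher in the other 3 arrays than in wt E16 changed by a median of -0.7238 where -3.74 was needed. RNA of wt E16 cells may be a source: 94 genes at least 8-fold higher in wt E16 rose by a median of 2.981, against 2.91 for the share of 68.0% given by Nrl, and 88 of them rose by more than 1. That share would also lower the 45 genes by 1.43, about 2 times the -0.7238 found, and Mki67 at 10.63 lay above its wt E16 mean of 9.54, which keeps the question open, and no biological explanation was tested. Over all genes, the best share of wt E16 was 59%, fitted to this same array. It left a root mean square difference of 0.268 (log2), against 0.536 without a mixture. The next best source, ko E16, left 0.384.

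The markers of amacrine, horizontal and ganglion cells were lower in ko from E16 to P10, although with an estimated correlation the calls at P6 and P10 were lost (adjusted p = 0.156 and 0.371). The called members differed between stages: Nefl, Nefm, Pou4f1 and Gap43 at E16, and Tfap2b, Gad1 and Calb1 at P10. At P10 Prox1 lay at 9.67 in ko and 9.37 in wt, so that not all members followed the list. The array spread is argued against as the cause, since with the preset correlation the list was called at 4 of 4 stages with the spread as a covariate. In wt P2 replicate 1 the list lay at 7.08, nearer to ko (6.93 to 6.99) than to the other wt arrays (7.62 to 7.69). Cells of these types in the sort of wt may be the source, and the sort for GFP would remove them only as far as they lack it. The members varied together within groups with a mean r of 0.09266, above the 95th percentile of random sets (0.0668), but 12 of 17 other lists had a higher value (median 0.143), so that it cannot be told apart from an effect of the genotype within the sorted cells.

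The spread of the arrays was the leading axis of variation. A scale left by the normalization of the authors is argued against, since after quantile normalization the leading component (31.71% of variance) still followed the original spread with an absolute r of 0.9585. Genotype and stage are argued against as the main source, since the groups held 29.58% of the variance in spread (permutation p = 0.254). RNA or amplification quality may be a source, since the spread followed the Actb 3' minus 5' signal within groups (r = 0.7664). The Gapdh signal went the other way (r = -0.512, permutation p = 0.0549), and a lower spread shrinks any log2 difference, that of Actb included.

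Other splits of the same arrays were compared with the real ones, out of 35 for each contrast. Only the real split gave as many genes at P2 (63, highest other 0), P6 (281, 169) and 4 weeks (860, 52). A share of 1 in 35 is the smallest that these splits allow. It was not adjusted over the contrasts, so that it weighs against chance without excluding it. At E16 4 splits, the real one included, gave as many genes (205, 612), and at P10 2 did (512, 791). The other split at P10 set ko replicate 1 and wt replicates 1, 2 and 4 against the rest. It followed the spread except that wt replicate 4 (1.571) lay above ko replicate 3 (1.561). With the spread as a covariate only the real split gave as many at P10 (1754, highest other 4), and at E16 2 splits did (677, 1080).

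For the steps in wt, only the real split gave as many genes from E16 to P2 (722, highest other 105). The same held from P2 to P6 (27, 5), but with the spread as a covariate 6 splits did (122, highest other 758). From P6 to P10 (64, 5773) and from P10 to 4 weeks (971, 6290) 4 splits each gave as many. In ko only the real split did from P6 to P10 (250, 9) and from P10 to 4 weeks (189, 9). For the steps, too, a share of 1 in 35 does not exclude chance. For the E16 to P2 and P2 to P6 steps in ko, residuals of arrays with the same replicate number correlated positively, and whether these arrays are true pairs is not known. If they are, the 8 splits that part as many pairs are too few for a share under 0.05 (182 and 120 genes, highest other 19 and 0). The other splits left at least 1 pair together and reached 8764 and 21 genes, so that 4 and 1 of all 35 were as large, and 1 each with the spread as a covariate (786 and 702, highest other 508 and 5). The splits with 5773, 6290 and 8764 genes point to a structure of the arrays other than the groups. With the spread as a covariate the P10 to 4 weeks step in wt was left with the real split alone (1752, highest other 574), and 3 splits gave as many for P6 to P10 in wt (475, highest other 2944).

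For the interaction, 1 of 100 regroupings within stages, the real one, gave as many genes (571, highest other 373). The number of lists called does not exclude chance at any stage: 11, 12, 19, 16 and 12 of 35 splits gave as many from E16 to 4 weeks (6, 6, 6, 6 and 9 lists; highest other 11, 10, 10, 9 and 12). The count of lists therefore carries little, while the p of the rod list from P2 on and of the cone list from P6 on was the smallest of the 35 splits. For the cone list at P2 2 splits gave a p as small, for the amacrine, horizontal and ganglion cell markers 3, 2, 3 and 1 did from E16 to P10, and for the other called lists between 1 and 34 did.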

How the results depend on the processing

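The fits without 6 doubted arrays and with the array spread as a covariate were chosen after the data were seen, and the other alternatives were planned. The cause of a change in a count was not tested, except that fewer arrays, a fold minimum and more probe sets change counts by construction. Counts for ko against wt are given in the order E16, P2, P6, P10 and 4 weeks, and for steps from the earliest to the last.

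Without the 6 doubted arrays the counts were 675, 205, 757, 1197 and 1389 for ko against wt, 8041, 297, 389 and 577 for the wt steps, 6789, 620, 1096 and 595 for the ko steps and 1297 for the interaction. With the array spread as a covariate they were 677, 339, 1641, 1754 and 2028, 232, 122, 475 and 1752, 786, 702, 1778 and 931, and 2313, with 2 lists at E16. Array weights gave 2246, 837, 4194, 7942 and 2920, 9425, 665, 5140 and 10438, 10906, 6003, 4134 and 1917, and 7326, with 5 lists at 4 weeks. The weights lay between 0.0628 (ko E16 replicate 3) and 5.36 (wt 4 weeks replicate 3).

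With the Actb 3' minus 5' signal as a covariate the counts moved to 312, 137, 1090 and 2010 at E16, P2, P6 and 4 weeks, 275 and 67 for the earliest 2 wt steps, 3884, 494, 1004 and 342 for the ko steps and 902 for the interaction. Cyclic loess moved them to 136, 610 and 800 at P2, P6 and P10, 64 and 177 for the wt steps P2 to P6 and P6 to P10, 312, 369, 791 and 302 for the ko steps, 894 for the interaction and 3 lists at E16. Quantile normalization gave 171, 689 and 945 at P2, P6 and P10, 403, 65 and 278 for the earliest 3 wt steps, 307, 354, 788 and 331 for the ko steps and 1031 for the interaction.

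Of the called genes, at least 2-fold changes were shown by 97 at E16, 161 at P6, 323 at P10 and 483 at 4 weeks, 295 and 535 for the earliest and last wt steps, and 96, 133 and 102 for the ko steps E16 to P2, P6 to P10 and P10 to 4 weeks. Every probe set on its own gave 595, 606, 836 and 2004 at E16, P6, P10 and 4 weeks, 1521 and 2210 for the earliest and last wt steps, 338, 472 and 372 for those 3 ko steps and 1124 for the interaction. The mean of all probe sets gave 10 for the wt step P2 to P6. With only the arrays compared, limma called 17, 38 and 210 at E16, P2 and P10, 7017, 16, 4 and 87 for the wt steps and 0, 186, 927 and 324 for the ko steps. Of the 18193 genes in the E16 to P2 step in ko, 1006 had an unadjusted p under 0.05 in this fit and 2386 in the fit of all arrays. The former is near the share of 0.05 that chance alone gives.

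With an estimated correlation 1, 2, 2, 2 and 2 lists were called from E16 to 4 weeks, with fry 2, 3, 3 and 4 at E16, P2, P6 and 4 weeks, and with the filter on detection calls 2 at E16 and 5 at 4 weeks. The direction of the test turned for 4 lists. Without the 6 doubted arrays the medians at P10 were -0.31 for cilium transport and -0.17 for synapse genes, and that of cell cycle genes at 4 weeks was -0.0229. It was 0.0118 with array weights, where the test turned, and with each array left out it lay between -0.0229 (without ko 4 weeks replicate 2) and 0.44 (without ko 4 weeks replicate 4). With the Actb covariate the median of oxidative phosphorylation at P10 was -0.18.

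With each array left out in turn, the counts lay between 60 and 507 at E16, 26 and 119 at P2, 147 and 323 at P6, 293 and 1536 at P10 and 712 and 779 at 4 weeks. For the wt steps they lay between 128 and 1485, 12 and 28, 35 and 249, and 479 and 3963, and for the ko steps between 17 and 7398, 55 and 280, 97 and 427, and 112 and 247. For the interaction they lay between 454 and 1018, and for lists between 5 and 8 at E16 and P2, 6 and 8 at P6, 6 and 7 at P10, and 5 and 9 at 4 weeks.

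Of the 144 named values 0 turned direction under any of these alternatives. The call was lost for 37 with only the arrays compared, 9 with the mean of all probe sets, 7 with the Actb covariate, 6 each with cyclic loess, the 2-fold minimum and without the 6 doubted arrays, 3 after quantile normalization and 1 each with every probe set, trend and robust variances and the replicate block. With 1 array left out 1057 of 1129 values kept their side of the threshold. The replicate block, trend and robust variances and the filter at the median changed no count by more than 1.5 times. Signal over background limits the folds of dim genes, which are lower bounds. RNA quality stayed on the same side of the threshold with Gapdh in place of Actb, where the difference at P10 was -1.17 (adjusted exact permutation p = 0.357).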

Other observations

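The regulators, lists and single genes below follow the planned comparisons, and no test in this part was chosen after the result was seen. Of the 22 lists, 8 were not called by camera at any stage, the lowest adjusted p being 0.0591 for vessel markers at P2, and fry called 1 of these 8, the visual cycle at 4 weeks. The visual cycle list (12 measured) held 1 fallen gene at P10, Dhrs3, and 2 at 4 weeks, Dhrs3 (-3.51, SE 0.31) and Rdh12 (-1.73, SE 0.35), with 2 fallen over the list alone at P10 and 3 fallen and 1 risen at 4 weeks, and at 4 weeks the list did not pass with camera (adjusted p = 0.198) but passed with fry (0.0219). Bipolar cell markers (12 measured) moved apart: Prkca, a kinase of rod bipolar cells, fell by 1.27 at P2 and by 1.85 at 4 weeks, while Pcp2 rose by 3.42 at P6 and 1.26 at P10, and the calcium-binding Cabp5 rose by 0.97 at 4 weeks.

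Of 16 markers of Müller glia, Apoe rose by 0.79 (SE 0.14) at P10 and the water channel Aqp4 fell by 1.35 (SE 0.20) at 4 weeks. Of 16 apoptosis genes, 1 fell at 4 weeks, Bcl2l11 (-1.50). Of 20 Wnt and BMP genes, 1 rose at P10, Ctnnb1 (0.26). Of 13 lens genes, Cryba1 fell by 2.43 at E16 and Cryab by 1.65 at 4 weeks, of 12 vessel markers Cldn5 fell by 0.43 at E16, and of 7 blood genes 0 were called by limma at any stage.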
